A study of Mus musculus with 6 samples.

How the data were processed

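Ribosomal RNA-depleted total RNA of mouse motor neurons from the cervical and thoracic spinal cord at e12.5 was sequenced in 6 libraries, 3 per region, all from control embryos without treatment per the labels. RNA was purified with a kit for very small samples, and stranded libraries were made from 10 to 20 ng of RNA with 15 PCR cycles, per the labels' protocols. How the motor neurons were isolated, how many embryos went into a library and which sequencer was used are not given in the sources used here.

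The deposited values are whole-number counts of reads per gene for 56805 genes listed by symbol with mm39 coordinates. Reads were checked with FastQC 0.11.9, aligned with STAR 2.7.5b and counted with featureCounts 2.0.1, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense partner that shares its exons cannot be told apart. Among the genes with values given, this includes Hoxa3 with Hoxaas2 and Gm29430, Hoxa4 with Gm29430, Hoxb3 with Hoxb3os, Hoxb5 with Hoxb5os, Hoxd3 with Hoxd3os1, Rarb with Top2b, Kcnip4 with 5730480H06Rik, Jun with Junos, Zeb2 with Zeb2os, and Gm10830 with Gm28265. Adamts9, Fn1, Gata3, Nkx2-2, Nos1, Pou3f1, Shh, Sv2b and Wnt11 have such partners with a mean of at most 22.5 counts. On the same strand, Hoxc5 and Hoxc10 share 166 exonic bases, and Hoxd3 shares 388 with Hoxd4 and 2225 with Gm28230. The values of all these genes are uncertain to that extent. The supplied reference genome is of another build and was not used for coordinates.

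Deposited counts summed to 32441442, 33790634 and 32103071 in cervical replicates 1, 2 and 3, and to 53186131, 32635514 and 32778156 in the thoracic replicates. The 37 mitochondrial genes have a count of 0 in all libraries. Named ribosomal RNA genes took 0.281 to 0.434% of counts and the 10 most abundant genes 5.60 to 6.11%. Within a region, pairs of libraries differed by 11.5 to 18.6 times the counting noise (chi-square per degree of freedom, over genes with at least 10 reads in the pair), so each library was counted as a separate sample. The labels mention no molecular identifiers, so the counting noise of this comparison takes each read as a separate molecule. Standard errors and SDs given below include the spread between libraries.

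Genes were kept by the default low-count filter of edgeR 4.0.16 in R 4.3.3, with a minimum count of 10. This left 21972 genes and removed 34833 genes that held 0.117% of the counts. Counts were scaled by TMM (factors 0.989 to 1.01) and tested with edgeR's quasi-likelihood test, with region as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are cervical minus thoracic with edgeR's prior count of 0.125, and the standard error is the size of the fold change divided by the square root of the F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. The common biological coefficient of variation was 15.4%. The median log2 fold change of all tested genes lay between 0.0069 and 0.0102 under TMM, median-of-ratios and library-total scaling.

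Before the data were examined, 37 gene lists were fixed. They cover Hox paralog groups, Hox non-coding RNAs and cofactors, motor columns, adhesion and guidance families, trophic receptors, signalling pathways, neuropeptides, maturation and proliferation, other cell types, stress response and sex-linked genes. The 36 lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with a correlation estimated per list, and with fry. The rule for naming genes was fixed at the same point. It took every tested Hox gene, the 10 other called genes with the largest fold change in each direction (mean CPM of at least 1 in the higher region, no overlap between regions), up to 4 members per list with the smallest adjusted p plus its most abundant member, and any member of the motor column lists. Cbx5, Gm49477, Fn1, Tmtc1 and the genes of the interneuron class and floor plate lists in the closing section were chosen after their values were seen. Some genes that the rule covers are not reported here.

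The test was run on 6 sets of simulated counts made from the real means, library sizes and dispersions, with 200 changed genes in each. A further short list was raised 1.5-fold, and its calls counted as true. Genes were drawn independently and without replicate pairs. Of the 200, the test called 34.1% of genes changed 1.5-fold, 59.2% of those changed 2-fold and 88.4% of those changed 4-fold, with 21474 genes tested on average. Of 822 calls, 83 (10.1%) were false, with 5.47 to 15.4% per set, which is above the rate that the 0.05 threshold aims at.

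Replicate numbers come from the sample titles and are shared by the regions. Deviations from the region means correlated at 0.163, 0.160 and 0.195 between cervical and thoracic libraries of the same number across all tested genes. Without genes of the sex chromosomes the values were 0.140, 0.138 and 0.121, and no pair of different numbers exceeded -0.0116. As all 3 exceeded 0.1, the numbers were taken as pairing the samples, which is a reading of the data and not of a label. The fit with the replicate number as a block is therefore given where it changes the call of a gene whose value is given, or the number of called members of a list. Alternatives were median-of-ratios and library-total scaling, no filter and a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, a stricter threshold, a test against a fold of 1.5, rank-based and estimated-correlation list tests, leaving out ribosomal RNA and haemoglobin genes, and leaving out each library. Thinning thoracic replicate 1 to the depth of the others was added after seeing the data.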

Results

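The data compare gene expression of motor neurons taken from the cervical and thoracic spinal cord of mouse embryos at e12.5, with 3 biological replicates per region. The series title places the comparison in a study of Hox5 genes and motor neuron diversity. Cervical motor neurons include those of the phrenic column, which drive the diaphragm, and of the limb-innervating lateral column. Thoracic motor neurons include the preganglionic column, which controls autonomic ganglia. Library totals ranged from 32103071 to 33790634 counts, apart from thoracic replicate 1 with 53186131. Nothing in the labels says whether a replicate is a litter, an embryo or a pool, so p-values measure the spread between these samples.

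Genes called higher in cervical libraries included Hox genes of groups 2 to 8 and neighbours of Hoxc4, and those called higher in thoracic libraries included Hoxc9, Nos1, Mme and Sim1. Of 21972 genes tested, 119 differed between the regions in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 42 higher in cervical and 77 higher in thoracic libraries. At least a 2-fold difference was found for 6 of the former and 24 of the latter. All 119 had no overlap between the 3 cervical and 3 thoracic values, as did 3021 genes (13.7%) of all tested, where chance gives 10%. With the replicate number as a block, 432 genes differed, 126 higher in cervical and 306 higher in thoracic libraries, and these held all 119. The count was 41 without cervical replicate 2, 9 without cervical replicate 3, 37 without thoracic replicate 2 and 45 without thoracic replicate 3, and the number higher in thoracic was 50 without thoracic replicate 1. The genes called in every fit that left out a library were Hoxc4, Hoxc9, Fn1 (fibronectin) and Tmtc1, and the other 115 lost their call in at least 1 such fit. Of the 49 called genes that are named, 43, 17 and 5 kept their call without cervical replicates 1, 2 and 3, and 38, 19 and 19 without thoracic replicates 1, 2 and 3.

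Called Hox genes, which set position along the body axis, differed in direction by paralog group. Hoxc9, which specifies thoracic motor neuron fates, was 6.02-fold higher in thoracic libraries, at 200.04 ± 43.2 CPM against 33.2 ± 5.97 CPM (log2 fold change -2.59, SE 0.16, edgeR adjusted p = 1.8e-04). Hoxa9 was 2.46-fold higher in thoracic libraries (114.9 ± 32.2 against 46.6 ± 6.38 CPM, log2 fold change -1.30, SE 0.18, edgeR adjusted p = 0.0148). Hoxc4 was 2.21-fold higher in cervical libraries, at 243.0 ± 7.15 against 109.7 ± 22.5 CPM (log2 fold change 1.15, SE 0.12, edgeR adjusted p = 0.0084). The 3 Hox5 genes were all higher in cervical libraries. Their log2 fold changes were 0.67 (SE 0.10) for Hoxa5, 0.68 (SE 0.09) for Hoxb5 and 0.80 (SE 0.09) for Hoxc5, with edgeR adjusted p of 0.0207, 0.0148 and 0.0095. In thoracic replicate 1 Hox genes lay closer to the cervical libraries, with Hoxc4 at 135.5 CPM against 99.4 and 94.1 CPM in the other thoracic replicates. Thoracic libraries still held 208.4 ± 34.2 CPM of Hoxa5 against 332.0 ± 17.8 CPM in cervical ones.

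Of 39 Hox genes in the file, 29 were tested and 12 were called, 10 higher in cervical libraries and 2 higher in thoracic ones. Among Hox1-3 genes, 2 of 8 rose in cervical libraries, Hoxa2 (log2 fold change 1.08) and Hoxa3 (0.59), and 6 did when adjusted over the list alone. Among Hox4-5 genes, 5 of 7 rose, including Hoxa4 (0.94), and 6 did when adjusted over the list alone. Among Hox6-8 genes, 3 of 8 rose, Hoxb6 (0.55), Hoxc6 (0.88) and Hoxb8 (0.93), and 5 did when adjusted over the list alone. Camera called these lists toward cervical with adjusted p of 7.7e-13, 3.3e-34 and 1.7e-13. With an estimated correlation the adjusted p were 0.223, 0.105 and 0.105. The 4 Hox9 genes were called toward thoracic (camera adjusted p = 7.5e-14, and adjusted p = 0.0483 with an estimated correlation), but not with ranks (0.235). Within that list Hoxb9 had a log2 fold change of 0.55 (edgeR adjusted p = 0.210, blocked 0.00176), and adjusted over the list alone it counted as higher in cervical. The 4 Hox9 genes summed to 572 ± 101 CPM in cervical and 653 ± 66.3 CPM in thoracic libraries, with overlap between the regions. Hoxc8 had nearly equal levels, at 278.1 ± 21.3 and 289.5 ± 11.3 CPM. Of 12 Hox10-13 genes, Hoxa10 and Hoxc10 were tested, with log2 fold changes of -2.22 and -2.80 at mean levels of at most 2.43 CPM (edgeR adjusted p = 0.182 and 0.104, blocked 0.0945 and 0.0278), and both passed adjusted over the list alone. With the block, 5 Hox1-3, 6 Hox4-5 and 5 Hox6-8 genes were called higher in cervical libraries, among them Hoxb3, Hoxd3, Hoxb4 and Hoxb7 with edgeR adjusted p of 0.00218, 0.0379, 0.00044 and 0.0154. Of 9 Hox non-coding RNAs none passed over all genes and 5 passed adjusted over the list alone, all higher in cervical libraries, such as Hoxaas2 (log2 fold change 0.82, edgeR adjusted p = 0.122, blocked 0.00542). With the block 4 were called, all higher in cervical libraries. That list was called toward cervical (camera adjusted p = 1.6e-05, and adjusted p = 0.223 with an estimated correlation). The 9 TALE cofactor genes, whose proteins bind DNA with Hox proteins, were not called as a list (camera adjusted p = 0.1104, and 0.0312 without cervical replicate 2), and 1 passed adjusted over the list alone.

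**Figure D1:**
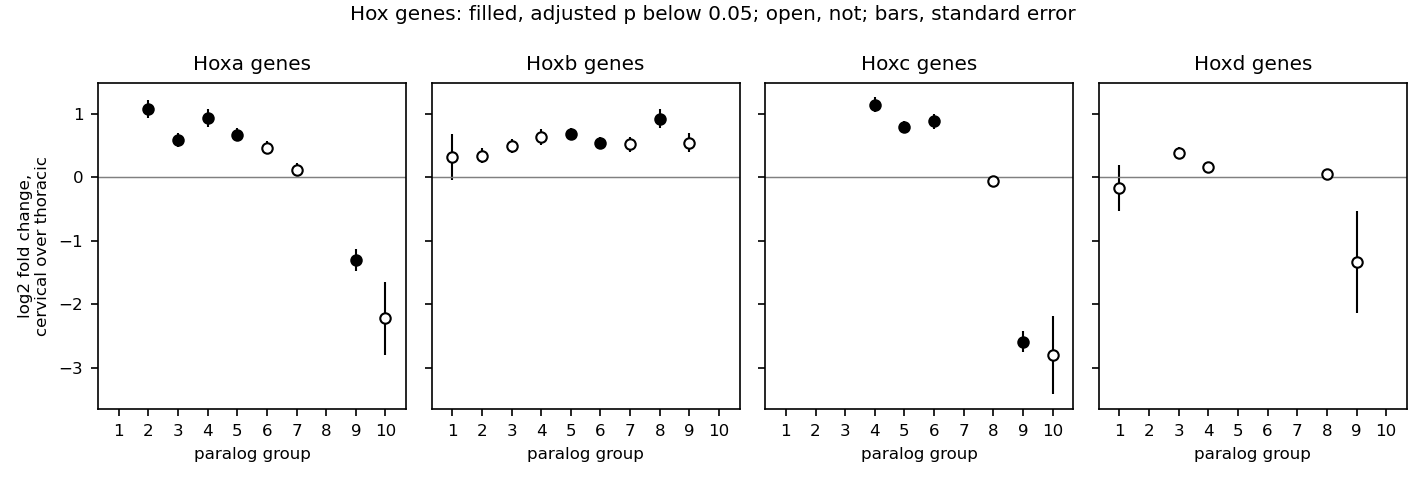
Log2 fold change of tested Hox genes, with 1 left out (cervical over thoracic, vertical axis), against its paralog group (horizontal axis), in 1 panel per Hox cluster, with bars for the standard error and filled points for adjusted p below 0.05. Called genes of groups 2 to 8 lie above 0, from 0.55 to 1.15, while Hoxa9 (-1.30) and Hoxc9 (-2.59) lie below 0.

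Among called genes other than Hox genes, the largest rise in cervical libraries was that of Smug1, which encodes a uracil-DNA glycosylase of base excision repair. It stood at 527.0 ± 20.2 CPM in cervical and 142.9 ± 67.0 CPM in thoracic libraries, 3.68-fold apart (log2 fold change 1.88, SE 0.24, edgeR adjusted p = 0.0110). Smug1 lies on chromosome 15 from 103061717 to 103075519 (mm39), 116 kb past the end of Hoxc4. Of the 6 tested genes that lie between them, 5 rose in cervical libraries, namely 5730585A16Rik (log2 fold change 0.98), Gm28876 (1.11), Gm10830 (1.07), Gm28265 (0.99) and D930007P13Rik (0.93). The sixth, Gm49477, had a log2 fold change of 0.09 (edgeR adjusted p = 0.967). Gm10830 and Gm28265 share 448 exonic bases on opposite strands, so their counts cannot be separated with certainty. Gm28265 was not called at a mean CPM of at least 1 (edgeR adjusted p = 0.0545) or with library totals only (0.0507). The next tested gene, Cbx5, stood at 659.3 ± 19.4 and 687.8 ± 44.1 CPM (log2 fold change -0.06, SE 0.06, edgeR adjusted p = 0.898). Elsewhere, Igf1, a growth factor, was 2.38-fold higher in cervical libraries (23.8 ± 6.16 against 10.1 ± 2.74 CPM, SE of log2 fold change 0.22, edgeR adjusted p = 0.0397, and 0.0511 at a mean CPM of at least 1). Moxd1 (log2 fold change 0.83), the opioid-related peptide precursor Pnoc (0.79) and the synaptic vesicle protein gene Sv2b (0.78) completed the 10 largest rises of called genes other than Hox genes.

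**Figure D2:**
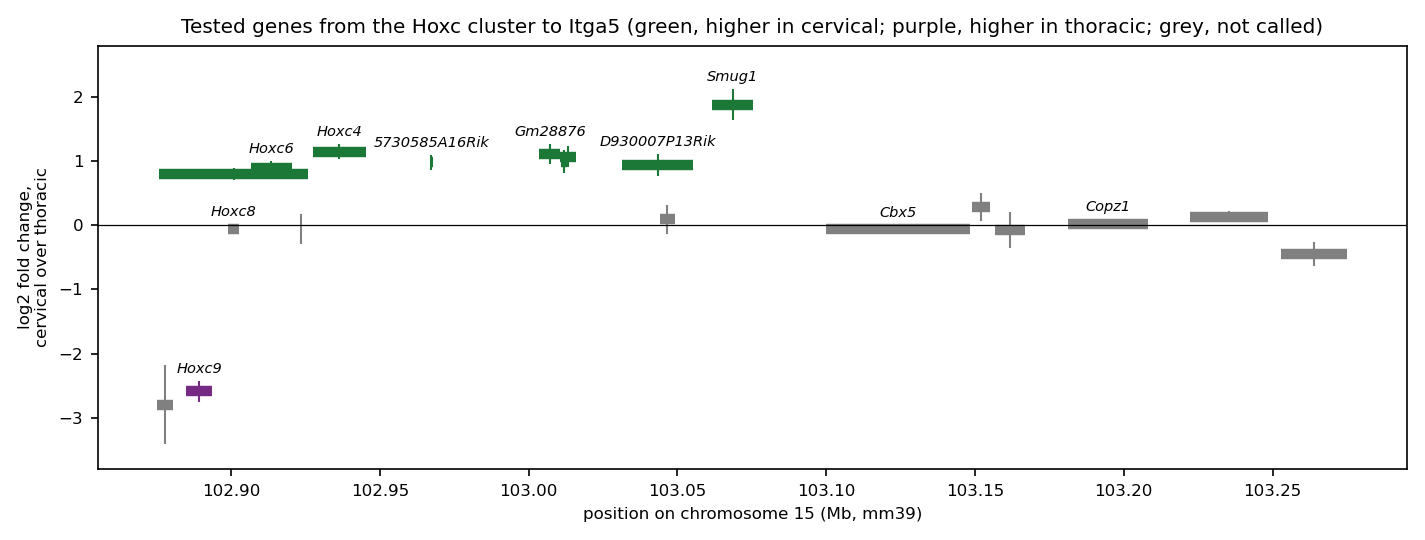
Log2 fold change (cervical over thoracic, vertical axis) of tested genes along chromosome 15 in mm39 (horizontal axis, Mb), with horizontal bars for gene extent and vertical bars for the standard error. Green genes were called higher in cervical and purple ones higher in thoracic libraries, and the run of green genes from Hoxc5 to Smug1 is interrupted by Hoxc9 in purple (-2.59) and by grey genes that were not called, among them Hoxc8 (-0.06).

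Among genes called higher in thoracic libraries, Nos1, the neuronal nitric oxide synthase, was 4.39-fold higher, at 37.1 ± 20.2 CPM against 8.41 ± 2.10 CPM (log2 fold change -2.14, SE 0.32, edgeR adjusted p = 0.0207). Mme, which encodes the peptidase neprilysin, was 7.02-fold higher, at 8.97 ± 4.92 against 1.27 ± 0.875 CPM (SE of log2 fold change 0.46, edgeR adjusted p = 0.0291). Sim1, a transcription factor of V3 interneurons, was 4.74-fold higher, at 27.5 ± 8.51 against 5.78 ± 3.11 CPM (SE of log2 fold change 0.33, edgeR adjusted p = 0.0192). The largest fold change of a named gene was that of Mgam at a low level, 1.31 ± 0.729 against 0.131 ± 0.0603 CPM (log2 fold change -3.26). The others were Pkd2l1, a channel gene of neurons contacting the cerebrospinal fluid (-2.38), Gm49677 (-2.36), the secreted ligand Wnt11 (-2.18), the metalloprotease Adamts9 (-1.79), Sytl2 (-1.61) and the potassium channel partner Kcnip4 (-1.48). Limma-voom did not call Mgam (adjusted p = 0.1195) or Gm49677 (0.0921), and the latter was not called at a mean CPM of at least 1 either (0.05004).

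**Figure D3:**
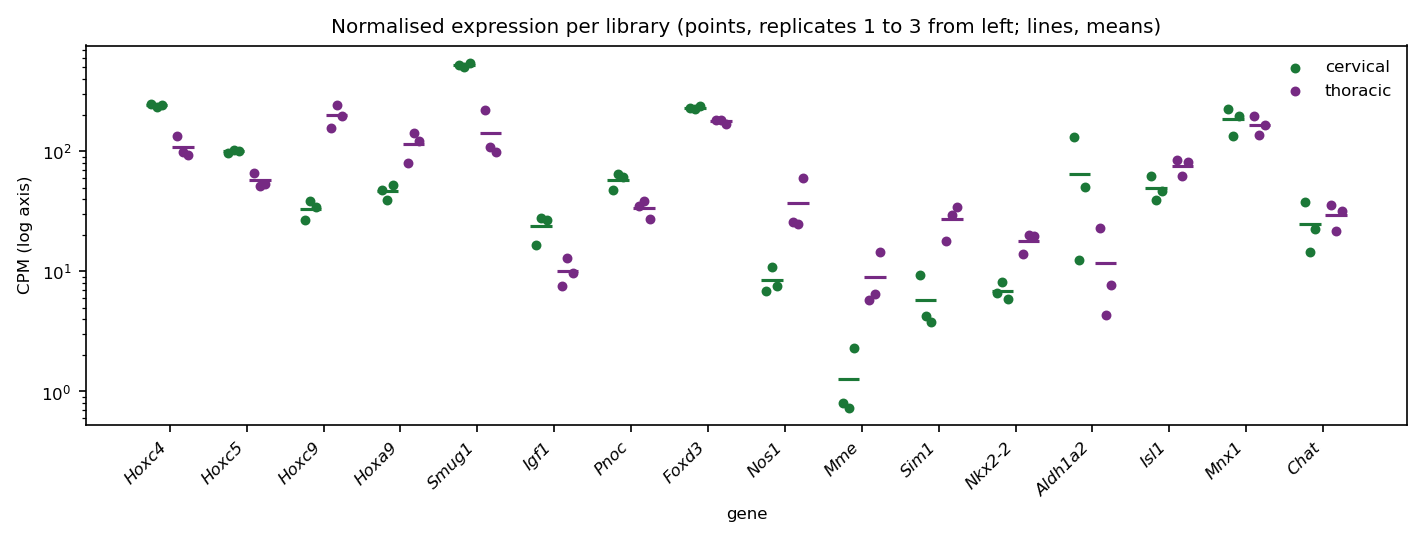
CPM (vertical log axis) of 16 genes in each library, with points for replicates 1 to 3 from left to right and lines for the mean, cervical in green and thoracic in purple. The regions do not overlap for Hoxc9, Smug1, Nos1 or Sim1, whereas values of Aldh1a2, Mnx1 and Chat overlap.

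Of 5 preganglionic genes tested, 3 rose in thoracic libraries, Nos1, Mme and Zeb2 (log2 fold change -0.40, SE 0.08, edgeR adjusted p = 0.0484), and 4 did when adjusted over the list alone, while 1 lay above 0. Limma-voom called none of the 3 (adjusted p of 0.0614, 0.0671 and 0.0653). Nos1 was not called without cervical replicate 3 (edgeR adjusted p = 0.1094), nor Mme without cervical replicate 2 (0.1094), thoracic replicate 2 (0.0608) or thoracic replicate 3 (0.0884). Zeb2 was called neither in the 6 fits that left out a library (0.0631 to 0.219) nor at a mean CPM of at least 1 (0.0521). The fourth, Fbn2, had a log2 fold change of -0.77 (edgeR adjusted p = 0.169, blocked 0.00036). Camera called the list toward thoracic (adjusted p = 2.4e-12, and adjusted p = 0.105 with an estimated correlation). Among 14 genes of the lateral column and limb pools, Lhx1 rose in cervical libraries (log2 fold change 0.45, edgeR adjusted p = 0.0256) and Nkx6-1 in thoracic ones (-0.54, edgeR adjusted p = 0.0261). Adjusted over the list alone, 4 were higher in cervical and 2 in thoracic libraries, and the block gave 4 and 2. Aldh1a2, the retinoic acid synthase of limb-level motor neurons, stood at 132.4, 12.6 and 50.4 CPM in the cervical replicates and 23.0, 4.36 and 7.78 CPM in the thoracic ones (log2 fold change 2.44, edgeR adjusted p = 0.279, blocked 1.7e-05). The list was called toward cervical (camera adjusted p = 0.0318, and adjusted p = 0.443 with an estimated correlation). It was not called without cervical replicate 1 (camera adjusted p = 0.703), thoracic replicate 1 (0.0717) or thoracic replicate 2 (0.0931), nor with limma-voom (0.0721).

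None of 6 phrenic column genes passed over all genes (camera adjusted p = 0.753), and adjusted over the list alone 1 was higher in each region. Tshz1 had a log2 fold change of 0.43 (edgeR adjusted p = 0.113, blocked 0.00119) and the adhesion gene Alcam one of -0.62 (edgeR adjusted p = 0.381, blocked 0.00053). Pou3f1 stood at 79.6 ± 15.4 and 83.5 ± 11.8 CPM. None of 12 genes common to motor neurons passed over all genes, and 1 was higher in thoracic libraries when adjusted over the list alone. Isl1 had a log2 fold change of -0.62 (edgeR adjusted p = 0.181, blocked 0.00105), Mnx1 one of 0.16 and Chat, which makes acetylcholine, one of -0.25. The list was called toward thoracic (camera adjusted p = 3.4e-04, and adjusted p = 0.443 with an estimated correlation), and the blocked fit called 4 members higher in thoracic libraries. Without cervical replicate 2 its adjusted p was 0.374. Of 6 hypaxial and medial column genes none passed (camera adjusted p = 0.181), though the list was called without cervical replicate 1 (0.0369). Of 6 genes of accessory and branchial motor neurons, Nkx2-2, also a gene of V3 progenitors, was higher in thoracic libraries (17.9 ± 3.48 against 6.87 ± 1.15 CPM, log2 fold change -1.37, edgeR adjusted p = 0.0104). Adjusted over the list alone 2 were, and the list was called toward thoracic (camera adjusted p = 0.0123, and adjusted p = 0.223 with an estimated correlation), though not without thoracic replicate 1 (0.1354) or with limma-voom (0.103).

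Interneuron genes differed in both directions and were abundant. Pax2, a gene of inhibitory interneurons, stood at 543.9 ± 25.5 CPM in cervical and 433.2 ± 14.9 CPM in thoracic libraries (log2 fold change 0.33, SE 0.06, edgeR adjusted p = 0.0462), above the 185.7 ± 47.3 and 166.4 ± 30.2 CPM of the motor neuron gene Mnx1. The glycine transporter Slc6a5 also rose in cervical libraries (log2 fold change 0.45, edgeR adjusted p = 0.0417). Neither was called in any of the 6 fits that left out a library (0.0761 to 0.154 for Pax2, 0.0528 to 0.167 for Slc6a5), nor Pax2 at a mean CPM of at least 1 (0.0535). Sim1, Lmx1b (-1.08, edgeR adjusted p = 0.0143) and Gata3 (-0.85, edgeR adjusted p = 0.0249) rose in thoracic ones. Of 23 interneuron genes, 2 rose in cervical and 3 in thoracic libraries, 7 and 6 did when adjusted over the list alone, and 3 and 4 with the block. The list was not called (camera adjusted p = 0.166), though it was without cervical replicate 1 (0.0256) and without thoracic replicate 3 (0.0425), with summed levels of 1766 ± 81.1 and 1564 ± 6.75 CPM. Neural progenitor genes summed to 1270 ± 197 CPM in cervical and 1521 ± 210 CPM in thoracic libraries. Genes common to motor neurons summed to 1381 ± 288 and 1609 ± 303 CPM. The samples thus held other neural cells, and these counts cannot assign a difference in a gene to motor neurons.

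Several other cell types left traces at lower levels. Erythroid genes summed to 16.98 ± 6.65 CPM in cervical and 9.48 ± 1.76 CPM in thoracic libraries, and macrophage genes to 12.1 ± 6.28 and 6.96 ± 2.62 CPM. Camera called both toward cervical (adjusted p = 0.00181 and 3.5e-04, and adjusted p = 0.223 and 0.348 with an estimated correlation). Mesenchyme genes summed to 185.6 ± 45.6 CPM in thoracic libraries and to 32.2, 82.6 and 238.5 CPM in the cervical replicates, and endothelial genes to 18.2 ± 3.58 and 14.8 ± 4.33 CPM in thoracic and cervical libraries. Both were called toward thoracic (camera adjusted p = 3.5e-04 and 0.0186, and adjusted p = 0.443 for each with an estimated correlation). Dorsal root ganglion genes summed to 112.9 ± 11.4 CPM in cervical and 94.2 ± 13.9 CPM in thoracic libraries (camera adjusted p = 0.0334, and adjusted p = 0.443 with an estimated correlation). No member of these 5 lists passed over all genes, while 2 erythroid genes and 1 ganglion gene did when adjusted over the list alone. With the block, 1 erythroid and 1 ganglion gene were called higher in cervical and 2 mesenchyme genes higher in thoracic libraries. Without cervical replicate 1 the adjusted p was 0.0724 for the erythroid, 0.0880 for the mesenchyme and 0.470 for the endothelial list. Without cervical replicate 2 it was 0.0688 for the macrophage and 0.769 for the ganglion list, and without thoracic replicate 1 it was 0.246 for the endothelial and 0.0633 for the ganglion list. The ganglion list was not called without thoracic replicate 3 (0.174), nor were the endothelial (0.0504) and macrophage (0.222) lists at a mean CPM of at least 1. Among Schwann cell and glial genes, Foxd3, which neural crest and V1 interneurons also express, rose in cervical libraries (231.2 ± 5.58 against 177.7 ± 8.22 CPM, edgeR adjusted p = 0.0207). That list summed to 300.9 ± 14.7 and 244.0 ± 4.36 CPM and was not called (camera adjusted p = 0.372), except without cervical replicate 1 (0.0256). Skeletal muscle genes summed to 8.29 ± 2.92 and 7.70 ± 1.54 CPM and were not called (camera adjusted p = 0.887, median log2 fold change 0.05, mean -0.09).

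Neuropeptide genes differed one by one. Pnoc rose in cervical libraries (edgeR adjusted p = 0.0400, and 0.0521 at a mean CPM of at least 1), while Cartpt (log2 fold change -1.35, edgeR adjusted p = 0.0369) and Adcyap1, which encodes PACAP (-0.86, edgeR adjusted p = 0.0207), rose in thoracic ones. Adjusted over the list alone 3 of 13 were higher in each region, with the block 2 in cervical and 3 in thoracic libraries, and the list was not called (camera adjusted p = 0.491). Among 15 trophic receptor genes, Met, the receptor of hepatocyte growth factor, rose in thoracic libraries (58.7 ± 12.9 against 32.7 ± 2.42 CPM, edgeR adjusted p = 0.0249). Adjusted over the list alone 1 was higher in each region, and with the block 1 in cervical and 3 in thoracic libraries. The list was not called (camera adjusted p = 0.131), except with the block (0.0474) and without cervical replicate 1 (0.0208). Among 16 cadherins, Cdh12 rose in cervical libraries (log2 fold change 0.67, edgeR adjusted p = 0.0302), 2 did when adjusted over the list alone, and the block called 2 higher in cervical and 1 in thoracic libraries. The list was not called (camera adjusted p = 0.753).

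Of 10 delta protocadherins none passed over all genes and 3 were higher in thoracic libraries when adjusted over the list alone, with Pcdh11x at a log2 fold change of -0.86 (edgeR adjusted p = 0.0599, blocked 0.00173). With the block 1 was called higher in cervical and 3 in thoracic libraries. The list was called toward thoracic (camera adjusted p = 0.0266, and adjusted p = 0.443 with an estimated correlation). Its adjusted p was 0.207 without cervical replicate 1, 0.312 without thoracic replicate 2, 0.154 without thoracic replicate 3 and 0.0739 with limma-voom. Guidance families were not called as lists by camera, which tests for a shared direction. Its adjusted p was 0.358 for 22 Eph receptors and ephrins, 0.181 for 31 semaphorins and their receptors, and 0.251 for 17 Netrin, Slit and Robo genes. For members moving in either direction, the unadjusted fry p was 0.304, 0.0340 and 0.00262 for these families. None of their members passed over all genes. Adjusted over the list alone, 1 semaphorin gene was higher in cervical libraries and 1 Netrin, Slit or Robo gene was higher in each region. With the block, 1 semaphorin gene was called higher in cervical libraries, and 1 Netrin, Slit or Robo gene higher in cervical and 2 in thoracic ones.

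Genes of retinoic acid signalling, which patterns the cervical cord, were called toward cervical as a list (camera adjusted p = 4.2e-05, and adjusted p = 0.348 with an estimated correlation), though not without cervical replicate 1 (0.0749). None of the 11 passed over all genes, and adjusted over the list alone 5 were higher in cervical and 1 in thoracic libraries. With the block 5 were called, all higher in cervical libraries. Dhrs3 had a log2 fold change of 1.32 (SE 0.35, edgeR adjusted p = 0.190, blocked 0.00229) and Cyp26a1 one of 1.80 (SE 0.42, edgeR adjusted p = 0.122, blocked 0.0258). The receptor gene Rarb, with a log2 fold change of 0.80 (edgeR adjusted p = 0.131, blocked 0.00049), shares 34.1% of its exonic length with Top2b on the other strand. Targets of FGF and of BMP and TGF-beta signalling were not called as lists (camera adjusted p = 0.561 and 0.0957), although the BMP list was without thoracic replicate 3 (0.0429), and none of their 9 and 12 members passed over all genes or over the list alone.

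Neuronal maturation genes were called toward thoracic (camera adjusted p = 0.0134, and adjusted p = 0.223 with an estimated correlation), though not without cervical replicate 2 (0.0745). Sv2c, a synaptic vesicle protein gene, rose in cervical libraries (302.9 ± 22.2 against 237.9 ± 5.48 CPM, edgeR adjusted p = 0.0484), though not at a mean CPM of at least 1 (0.0511) or with library totals only (0.0507). Adjusted over the list alone, 1 of 15 was higher in cervical and 2 in thoracic libraries, and with the block 1 and 4. Neural progenitor and cell cycle genes were also called toward thoracic (camera adjusted p = 0.0213 and 0.00182, and adjusted p = 0.501 and 0.443 with an estimated correlation). No member passed over all genes, and 2 of 14 and 1 of 15 were higher in thoracic libraries when adjusted over the list alone, and 3 and 1 with the block. The progenitor list was not called without cervical replicate 1 (adjusted p = 0.164), cervical replicate 3 (0.247) or thoracic replicate 2 (0.816), nor the cell cycle list without thoracic replicate 2 (0.176). Vim, an intermediate filament gene of progenitors, had a log2 fold change of -0.48 (edgeR adjusted p = 0.0859, blocked 0.00073). Mki67 had one of -0.31 (edgeR adjusted p = 0.130, blocked 0.0221). Neurogenic transition genes were not called (camera adjusted p = 0.664) and none of the 14 passed. Stress response genes, which tissue dissociation can induce, summed to 683.8 ± 9.69 CPM in thoracic and 555.3 ± 54.9 CPM in cervical libraries and were called toward thoracic (camera adjusted p = 3.5e-04, and adjusted p = 0.105 with an estimated correlation). None of the 14 passed, 2 were called higher in thoracic libraries with the block, and Jun had a log2 fold change of -0.33 (edgeR adjusted p = 0.314, blocked 0.0142).

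In all, camera called 20 of 36 lists, 9 toward cervical and 11 toward thoracic, and 1 with an estimated correlation. Fry, which asks only whether a list moves one way, called none (smallest adjusted p = 0.0687), with 9 at an unadjusted p below 0.05. Some lists that camera did not call had a low unadjusted fry p for members moving in either direction. Examples are cadherins (1.6e-04), neuropeptides (3.5e-04) and interneurons (2.3e-04). Among lists without a called member in edgeR, an unadjusted p below 0.05 was reached by 3 motor neuron, 2 phrenic, 0 hypaxial and medial, 5 Hox non-coding, 1 TALE and 2 Hox10-13 genes. DESeq2 called 1, 1, 0, 3, 1 and 2 genes of these lists. The same counts were 5, 1, 6 and 7 for delta protocadherins, Eph, semaphorin and Netrin, Slit and Robo genes (DESeq2 3, 0, 1 and 2), and 6, 2 and 2 for retinoid, FGF and BMP genes (DESeq2 2, 0 and 0). They were 3, 3, 0 and 5 for progenitor, cell cycle, neurogenic and stress genes (DESeq2 2, 1, 0 and 0), and 3, 3, 1, 0, 1 and 2 for erythroid, macrophage, endothelial, mesenchyme, ganglion and muscle genes (DESeq2 1 for ganglion, 0 for the others). Limma-voom called 0 in each of these lists. On simulated counts 10.1% of the calls of single genes were false, so some of the 119 genes near the threshold are uncertain. The simulated genes were independent and unpaired, so the rate for the 119 may differ.

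**Figure D4:**
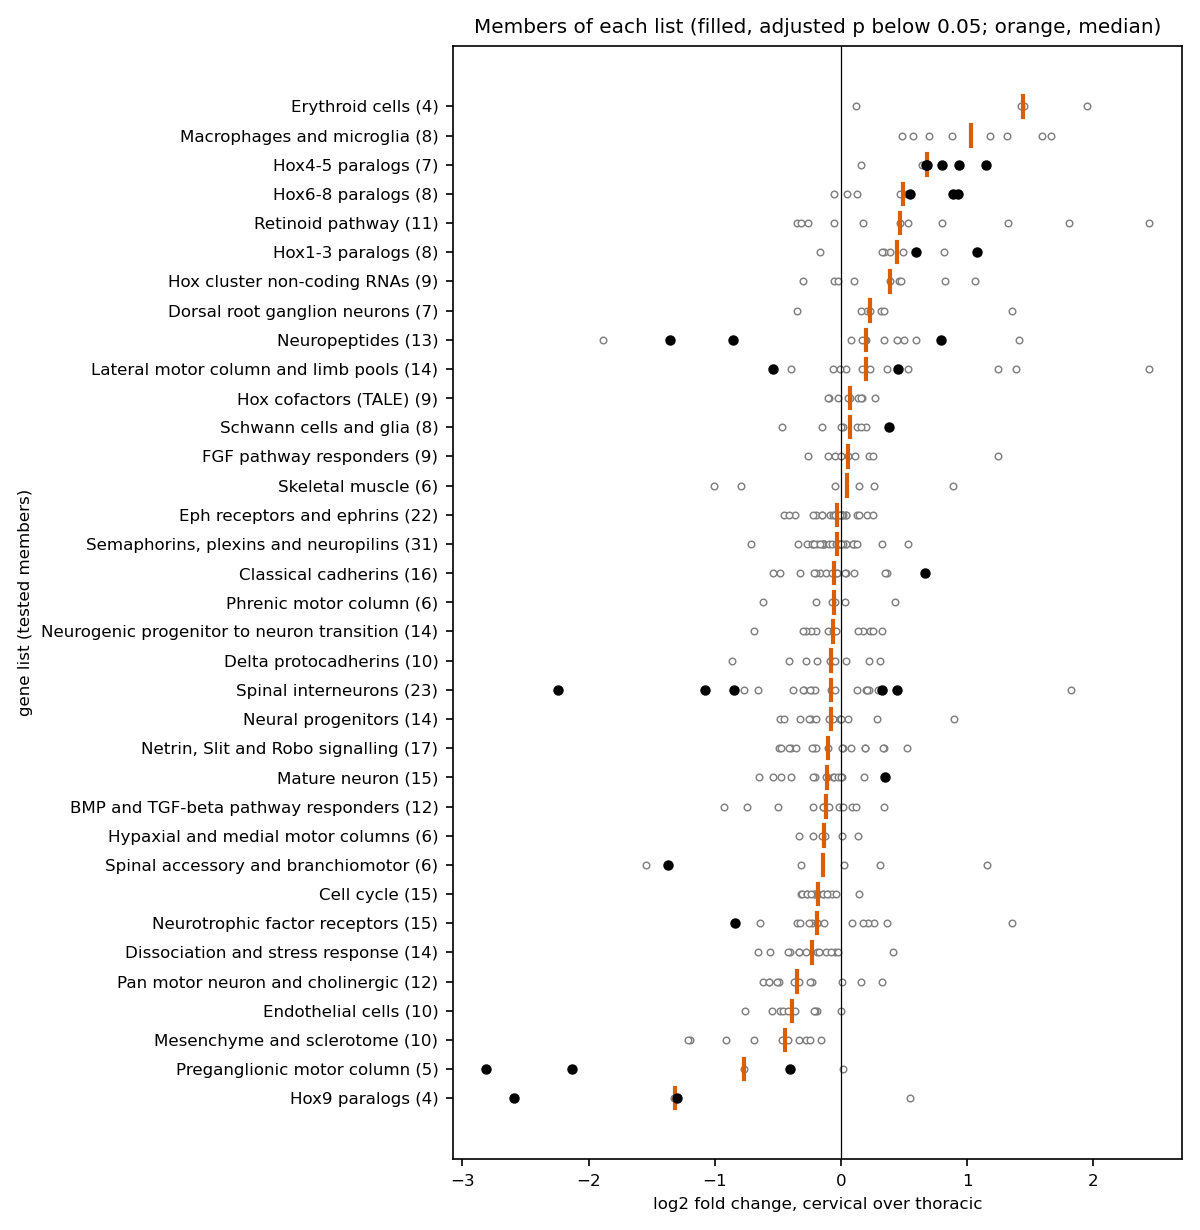
Log2 fold change (cervical over thoracic, horizontal axis) of the tested members of 35 gene lists (vertical axis, number of tested members in brackets), with filled points for adjusted p below 0.05, open points for the rest and an orange line for the median; sex-linked genes are left out. Called members are few in most lists, and those of the Hox4-5 and preganglionic lists lie on opposite sides of 0.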

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

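The 119 calls were tested under each alternative, with the thinning of thoracic replicate 1 the only one chosen after seeing the data. The number of calls was 747 without a low-count filter (232 higher in cervical, 515 in thoracic), 400 with DESeq2 (124 and 276) and 432 with the replicate block (126 and 306), each including all 119. It was 16 at an adjusted p below 0.01 (6 and 10) and 1 in the test against a fold of 1.5 (0 and 1). The cause of these changes was not tested, apart from the stricter criteria of the last pair. Leaving out a library gave 9 to 159 calls, 1 to 48 higher in cervical and 8 to 111 in thoracic, with fewer samples in each fit. No call changed sign in these fits. Between 95 and 125 genes were called with other scalings, limma-voom, a mean CPM of at least 1, ribosomal RNA and haemoglobin genes left out or thoracic replicate 1 thinned. Of 36 lists, 1 was called with an estimated correlation (0 toward cervical, 1 toward thoracic) and 13 with ranks (7 toward thoracic), which lost the Hox9 (0.235), lateral column, accessory, delta protocadherin, retinoid, progenitor and ganglion lists. Of the 20 called lists, limma-voom kept 17, a mean CPM of at least 1 kept 18, and leaving out a library kept 13 to 19, with 13 and 4 added without cervical replicate 1. The 7 kept in every fit that left out a library were those of Hox1-3, Hox4-5, Hox6-8, Hox9, Hox non-coding, preganglionic and stress genes. The block added the trophic receptors and lost no list. Uncalled log2 fold changes that changed direction were those of Mnx1 (-0.011 to 0.34), Chat (-0.67 to 0.026), Pou3f1 (-0.21 to 0.064), Hoxd9 (-1.85 to 0.17), Gm49477 (-0.058 to 0.19) and Hoxd8 (-0.019 to 0.15), over the fits that left out a library. Uncalled lists that did so, with their camera adjusted p and its range over the same fits, were neuropeptides (0.883 without filter), sex-linked genes (0.931 with limma-voom, 0.986 with ranks, 0.174 to 0.757), skeletal muscle (0.963 thinned, 0.104 to 0.769), neurogenic transition (0.113 to 0.858), glia (0.0256 to 0.667, called without cervical replicate 1) and cadherins (0.265 to 0.861). Hoxc10 and Hoxa10 lay at or below 2.43 CPM, DESeq2 called both, and the effect of depth on them was not tested.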

Other observations

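Tests on interneuron class and floor plate lists, on the position of thoracic replicate 1 between the regions, on the ratio of interneuron classes and on the Hoxc4 to Smug1 interval were chosen after the results were seen. The counts over other splits of the libraries were set out before their results were seen. The thinning was added after seeing the data, but its prediction was set out before its own result was seen. Of 10 genes of V1 inhibitory interneurons, 4 were called higher in cervical libraries (Foxd3, Lhx1, Pax2 and Slc6a5), with 8 above 0 and 2 below 0 (log2 fold changes from -0.22 to 0.45). Their summed level was 2232 ± 15.7 CPM in cervical and 1763 ± 52.0 CPM in thoracic libraries. Lhx1 also belongs to the lateral column list and Pax2 and Slc6a5 mark further inhibitory classes. Of 5 genes of V3 interneurons, 4 were called higher in thoracic libraries (Sim1, Nkx2-2, Olig3 and Lmx1b), all 5 lay below 0, and they summed to 137.9 ± 11.7 against 72.7 ± 10.1 CPM. Of 5 genes of V2b and cerebrospinal fluid contacting neurons, 2 were called higher there (Gata3 and Pkd2l1), with 4 below 0, 1 above 0 and a median of -0.38 (SE 0.535), and they summed to 54.4 ± 7.05 against 35.2 ± 3.41 CPM. Adjusted over the 7 lists, camera with an estimated correlation gave p of 0.0156, 0.00272 and 0.0260 for these lists, and 0.144, 0.149, 0.740 and 0.740 for floor plate, V2a, V0 and dorsal excitatory genes, none of whose members were called without the block. As the lists were chosen after the results were seen, their p-values describe them and cannot test whether the classes differ. With the block, the V1 genes Foxp2 and Otp (edgeR adjusted p = 0.0220 and 0.0219) and the V3 gene Uncx (0.0152) were called as well. So were the dorsal excitatory genes Lhx9 (0.00656) and Prrxl1 (0.00933) and floor plate genes named below. Fry with the block called none of the 7, with adjusted p of 0.0562, 0.0562 and 0.0931 for the V1, V3 and V2b lists.

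The 8 floor plate genes, such as Shh and Foxa2, all had negative log2 fold changes (median -0.9998, blocked edgeR adjusted p of 0.00649 for Shh and 0.0354 for Foxa2), and their summed level was 456.2 CPM in cervical replicate 1 against 989.9 to 1524 CPM in the other libraries. Xist, transcribed from the inactive X chromosome of females, stood at 0.992 to 2.39 CPM in replicates 1 and 2 of both regions and at 2166 and 2010 CPM in replicate 3. Xist and the Y chromosome genes of the sex-linked list together summed to 228 to 249 CPM in replicates 1 and 2 and to 2167 and 2011 CPM in replicate 3. Sex thus differed between replicate numbers and matched between regions of the same number. Libraries of mixed sex are argued against, while 1 embryo and a pool of 1 sex cannot be told apart. The list of sex-linked genes did not differ by region (camera adjusted p = 0.922). Other splits of the 6 libraries called 0 genes at most against 119, and 15 lists at most against 20, with 1 split of 10 as large in each case. The other 3 splits that part all 3 pairs gave 0 at most against 432 with the block, so that 1 of these 4 was as large. The splits are too few for a share under 0.05. The preset correlation thus called up to 15 lists in splits that mix the regions.

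The median log2 fold change of V1 genes was above 0 and that of V3 genes below 0, although 2 of 10 V1 genes lay below 0 and 4 of the 10 were called without the block. A lower share of motor neurons in 1 region would raise all other cell types alike. The medians of V1 and V3 genes lay 1.62 apart (SE 0.377, taken over genes). Both lists were chosen after their values were seen, with V1 genes called higher in cervical and V3 genes in thoracic libraries. The distance therefore cannot test that share. Called interneuron genes of the list fixed beforehand lay on both sides of 0, which that share alone would not give, while a part played by it stays open. Those above 0, Pax2 and Slc6a5, lost their call in every fit that left out a library, so that side is uncertain. Leaving out cervical replicate 1 cannot test whether less ventral midline tissue in it alone lowered the V3 genes, which were chosen after their values were seen. Without that library their median was still -1.35 (SE 0.466 over genes). They summed to 84.2 CPM in cervical replicate 1 against 65.4 and 68.5 CPM in cervical replicates 2 and 3, so it was not the lowest. The median of floor plate genes moved from -0.9998 to -0.59 (SE 0.088 over genes) and stayed below 0. A regional difference in the number or maturity of interneurons, or in how ventral tissue was taken at each level, may account for the pattern and was not tested.

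Smug1 and 5 of the 6 genes between it and Hoxc4 were higher in cervical libraries. Reads running on from Hoxc4 would add less with distance, but the excess of cervical over thoracic CPM per kb of exon in Smug1 was 5.06 times the highest of the genes between (2.95 times with the least favourable libraries). Such reads are argued against as the whole cause for Smug1 and stay open for the genes between. Smug1, 5730585A16Rik, Gm28876, Gm28265 and D930007P13Rik lie on the strand opposite to Hoxc4. Reads running on from Hoxc4 could count for them only if the counting ignored the strand, and its setting is not given. Gm10830 and Gm49477 lie on the strand of Hoxc4. Chance placement is argued against as well, since 6 called genes started within 200 kb of each other, against at most 3 in 1000 random placements (permutation p = 0.000999, the smallest they can give). A shared regulatory domain that ends before Cbx5 is a hypothesis that was not tested, and Gm49477 within the interval had a log2 fold change of 0.09 (edgeR adjusted p = 0.967).

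Thoracic replicate 1 lay toward the cervical libraries in its Hox genes, with a median position of 0.414 (95% interval 0.350 to 0.498) on a scale from 0 at the other libraries of its own region to 1 at those of the other region. The interval takes its 16 Hox genes as independent, and does not measure the spread between libraries. Thinning thoracic replicate 1 to the depth of the others left the position at 0.412. Thinning leaves expected CPM unchanged, so this outcome was nearly fixed in advance and cannot judge the effect of depth. Cervical cells or RNA in thoracic replicate 1 cannot be told apart from a more anterior dissection. Either may shift Hox and non-Hox regional genes alike, so the position of non-Hox genes cannot separate them. Non-Hox regional genes of that library lay at 0.339 (0.269 to 0.408, permutation p = 0.315 for the difference, over genes). In such genes cervical replicates 1, 2 and 3 lay at 0.305, 0.132 and 0.09998, each placed between its own region and the other. Thoracic replicates 2 and 3 lay at 0.281 and -0.055. In Hox genes these 5 libraries lay between -0.264 and 0.083. The Hox genes of thoracic replicate 2 lay below its non-Hox genes (difference -0.545, permutation p = 4.0e-04, over genes). A mixed sample or a boundary placed further forward may each produce the values of thoracic replicate 1.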
